A study of Homo sapiens with 6 samples.

How the data were processed

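Total RNA from 3 human cancer cell lines, A549, SAOS and H1299, was compared on 6 2-colour expression arrays. On each array 1 dye carried RNA of cells given an siRNA against ATAD2 and the other dye carried RNA of the same line given a control siRNA. Each line was hybridised on 2 arrays with Cy3 and Cy5 exchanged. Per the labels, both arrays of a line carried the same 2 RNA extracts, so a line was counted as 1 replicate and its 2 arrays as a technical dye swap.

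The values used were the log2 ratios that the authors deposited as a processed table, with 27648 features on every array and no missing value. The mean of each array was 0, so the authors had centred the deposited values. The array medians as deposited lay between -0.0151 and 0.0466. The log base, the numerator of the ratio, the scanner, the background correction and the normalisation are not given in the sources used here. Base 2 was assumed, and every fold value depends on it. Spot intensities and quality flags were not used here, so neither signal over background nor a level of expression stands behind a ratio, and the number of arrays limits the precision.

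The values were read as already turned to run the same way on all 6 arrays. ATAD2, the targeted gene, had a negative value on every array. As deposited, the 2 arrays of a line did not correlate clearly across probes, at r = 0.0490 in A549, -0.0457 in SAOS and -0.0926 in H1299. After the mean response of each dye orientation was removed, the 2 arrays of a line correlated across probes at r = 0.140 in A549, 0.164 in SAOS and 0.0990 in H1299. All 6 pairings of arrays from different lines and opposite dyes were negative after that step, from -0.114 to -0.0343, a sign that removing a mean partly forces. ATAD2 siRNA over control siRNA is therefore called the likely direction, and with the other numerator every sign below would turn. If the values were not already turned, the response would cancel in the line means below and dye effects would remain. Probes and genes are not independent replicates, so these correlations carry no p.

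On this reading dye effects were strong. Arrays of different lines with the same dye orientation correlated across probes at r = 0.372 to 0.498, and those with opposite orientation at -0.140 to -0.0298. The mean of the 2 arrays of a line cancels a dye effect that is equal in both. The slide numbers fell into 2 ranges, with the 2 A549 arrays in 1 range and the 4 SAOS and H1299 arrays in the other, so a slide batch and the difference of A549 from the other lines cannot be told apart.

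Probe names came from the platform's annotation, updated through accessions, symbols and synonyms of a RefSeq gene table. Of the 27648 probes, 17711 had 1 symbol, 0 had several and 9937 had none. Of the named ones, 14604 were matched by accession, 1814 by symbol and 1085 by synonym, and 91 kept the old name. A further 117 had a symbol and an accession of different genes and were left unnamed. ACTB stood on 321 spots and GAPDH on 272, and each was averaged to 1 value, which left 27057 probes, 17003 of them named. Other probes of a gene were kept apart in the probe test and averaged for the gene lists, which gave 14473 genes.

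Arrays were centred on their medians and the 2 arrays of each line were averaged. The common response was tested with limma (lmFit and eBayes on 3 line means against 0, two-sided), with Benjamini-Hochberg adjustment over 27057 probes and a threshold of 0.05. Nothing in the labels says that cells were treated more than once per line, so the p-values measure the spread between the lines. The smallest two-sided p of an exact sign-flip test of 3 lines is 0.25, so no exact test of a single gene could pass. Within a line there was no replicate, and probes were counted by size: both arrays at a log2 ratio of at least 1 in the same direction. Probes of the same size with opposite signs on the 2 arrays were counted beside them as a measure of dye effects and noise. They do not estimate how many of the probes past the rule are technical.

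Before the data were examined, the grouping, the tests, the alternatives listed last except those named there as added, 27 gene lists and the rule for named genes were fixed. The rule took ATAD2 first. Over the lines it took the 12 higher and 12 lower probes with 1 symbol that had the largest moderated t, the same direction on all 6 arrays and a mean of at least 0.58 in size. In each line it took the 6 higher and 6 lower probes with the largest means past the size rule, and for each list up to 4 members with the largest mean. FDXR, BBC3 and MDM2 were named after their values were seen. The lists covered E2F targets, G2/M and mitosis, MYC targets, p53 targets, apoptosis, histone genes, chromatin and bromodomain proteins, AAA ATPases, cancer-testis genes, interferon response, NF-kB and inflammation, hypoxia, the unfolded protein response, heat shock, cholesterol synthesis, oxidative stress with NRF2 targets, matrix and epithelial-mesenchymal transition, ribosomal proteins, the proteasome, oxidative phosphorylation, nuclear receptor targets, the RNA interference machinery and reference genes. Markers of lung epithelium, osteoblasts, blood cells and fibroblasts or endothelium completed them. Another 3 lists, for p53, NF-kB and NRF2, were added after the first lists' results were seen.

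Lists with at least 5 measured genes were tested over the lines with limma's camera (preset correlation of 0.01), with Benjamini-Hochberg adjustment over 27 lists. camera with an estimated correlation and fry were run beside it. Within a line, the median of a list was placed among the medians of 10000 random lists of the same size, drawn without matching on expression because no level was at hand. This describes the arrays of that line and is not a test.

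The procedure was tested on simulated data of 27057 features and 3 lines, with 200 changed features in each of 5 runs. At the adjusted threshold it recovered 0.299% of features changed by 0.6 on the log2 scale, 0.597% of those changed by 1 and 75.8% of those changed by 2, with 14 false calls over all runs. At an unadjusted p under 0.05 the shares were 82.1%, 94.9% and 98.5%. The shares recovered at the adjusted threshold depend on how many features change, and that number is not known for the real data. For lists, camera gave a p of 6.67e-25 for a simulated list of 30 genes shifted by 0.5 and 0.744 for an unshifted one, among 14473 genes. The simulated genes were drawn independently. The run therefore cannot show how often camera passes an unshifted list whose genes move together.

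Alternatives were no centring, scaling to one median absolute deviation, quantile normalisation, 6 arrays with the line as block, the same with a dye coefficient, a robust variance prior, leaving out the 25% of probes with the largest dye-swap difference, gene means, other size rules, and leaving out each line or array. Named probes alone, turned signs, an adjusted threshold of 0.10 and an AAA ATPase list without proteasome subunits were added after seeing the data. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.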

Results

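Transcript levels after knockdown of ATAD2, a nuclear protein with an AAA ATPase domain and a bromodomain, were compared with those after a control siRNA in 3 human cancer cell lines. A549 and H1299 derive from lung carcinomas and SAOS from an osteosarcoma. Each line was measured on 2 arrays with exchanged dyes, 6 arrays in all, and 27648 features had a value on every array. The comparisons ask which transcripts differ when ATAD2 is depleted, and whether the lines share them. Values are log2 ratios of ATAD2 siRNA over control siRNA, in the likely direction and with base 2 assumed.

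ATAD2 itself was lower on all 6 arrays. Its mean was -1.18 ± 0.08 (SD, n = 3 lines), which leaves 44.0% of the control level. The line means were -1.27 in A549, -1.17 in SAOS and -1.11 in H1299. The 2 arrays of a line differed more than the lines did, with -1.88 and -0.66 in A549, -0.74 and -1.60 in SAOS and -0.79 and -1.42 in H1299. ATAD2 was represented by 1 probe, and its adjusted p in the limma fit was 0.0732.

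Across the 3 lines, the named transcript with the lowest mean was STRAP, a WD-repeat protein that binds TGF-beta receptors, at -2.83 ± 0.29 (SD, n = 3 lines), or 7.13-fold lower. The cell cycle regulator cyclin D1 (CCND1) stood at -2.10 ± 0.37, and a further CCND1 probe at -0.67. SCRN1 had a mean of -2.03 ± 0.26, PAIP1, which binds the poly(A)-binding protein, -1.99 ± 0.31, and the ribosomal protein gene RPL14 -1.64 ± 0.05. ODC1, the first enzyme of polyamine synthesis, was higher at 2.15 ± 0.37, and RRM2, a subunit of ribonucleotide reductase, at 2.06 ± 0.20.

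The other transcripts with the largest moderated t on the higher side were MRPL15 (1.76 ± 0.23), the transcriptional repressor HES6 (1.63 ± 0.12), UBR7 (1.59 ± 0.15), the activin receptor ACVR2B (1.46 ± 0.10), NF2 (1.45 ± 0.15), PPP1R3B (1.44 ± 0.14), EIF4G2 (1.40 ± 0.13), EIF3C (1.35 ± 0.10), the NKG2D ligand MICA (1.33 ± 0.07) and SNRPA1 (1.30 ± 0.05). On the lower side were TMEM183A (-1.90 ± 0.31), ENY2 (-1.68 ± 0.26), FSTL1 (-1.55 ± 0.22), TMEM230 (-1.49 ± 0.18), DOK4 (-1.41 ± 0.17), EMP3 (-1.40 ± 0.03) and the chromatin-binding protein PSIP1 (-1.36 ± 0.15). Second probes were close for EIF4G2 (1.39), UBR7 (1.24) and EIF3C (0.97) and lower for NF2 (0.51). They did not show the difference for SNRPA1 (0.013), MICA (-0.26) or PSIP1 (0.0139 and 0.0501), so the values of these 3 genes rest on single probes. The named genes without a second probe, STRAP, ODC1 and RRM2 among them, also rest on 1 probe each. The SD covers the line means and not the arrays of a line, which lay far apart for some genes. PPP1R3B was at 0.72 and 2.42 on the SAOS arrays and at 0.72 and 2.21 on the A549 arrays. TMEM183A was at -2.58 and -0.51 on the H1299 arrays, and PSIP1 at -2.08 and -0.43 on the A549 arrays.

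**Figure D1:**
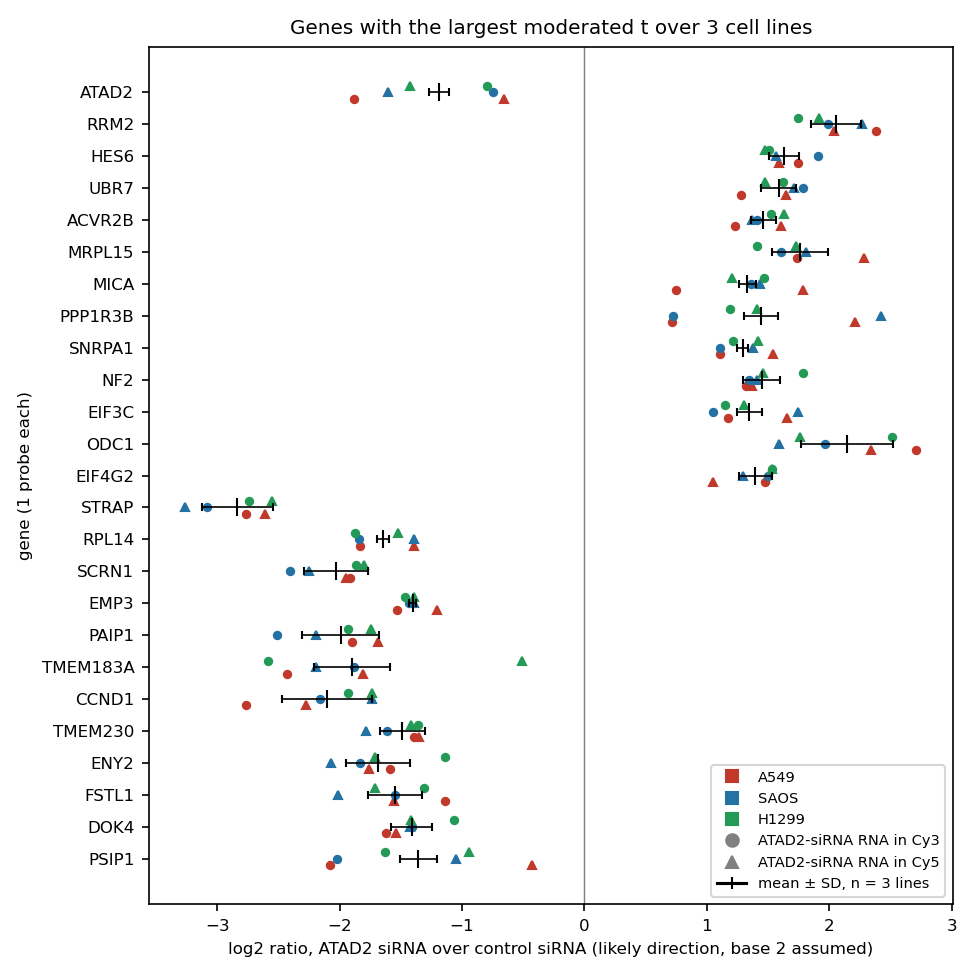
Log2 ratios of ATAD2 siRNA over control siRNA for ATAD2 and the 12 higher and 12 lower named genes, 1 probe each. Coloured points are single arrays by line and dye, and black bars give the mean ± SD of 3 lines; STRAP lies lowest at -2.83 and ODC1 highest at 2.15.

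In the limma fit of 27057 probes, 0 passed an adjusted p of 0.05, and the lowest adjusted p, shared by ATAD2 and the 24 others named above, was 0.0732. At an unadjusted p under 0.05 there were 4292 probes, 2285 higher and 2007 lower, against 1353 expected by chance. A total of 1794 probes were higher on all 6 arrays and 1492 lower. The count depended on the fit. When only named probes were tested, 98 probes passed. When unnamed probes were left out and a gene's probes were also averaged, 133 of 14473 genes passed. Without the 25% of probes that differed most between dye-swap arrays, 752 probes passed. Fits of 6 arrays with the line as block gave 2044 probes (consensus correlation of the arrays of a line -0.311), or 1561 with a dye coefficient (828 higher, 733 lower; 0.275). The limma adjusted p of ATAD2 was 0.00332 and 0.0516 in these 2 fits, 0.0313 without the 25% of probes and 0.0478 among named probes.

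Of 26 genes of the proteasome, which degrades ubiquitinated proteins, 23 were above 0, with a median of 0.32 over the lines. The list passed camera with its preset correlation (adjusted p 2.8e-05) but not with an estimated one (adjusted p = 0.631), nor fry (adjusted p 0.231). PSMD4 had a mean of 0.75 ± 0.35 (SD, n = 3 lines), PSMD8 0.68 ± 0.40 and PSMA2 0.67 ± 0.32. In oxidative phosphorylation 23 of 32 genes were above 0 (median 0.23), with UQCRFS1 at 1.09 ± 0.26 and ATP5F1A at 0.87 ± 0.12, while NDUFB5 was at -0.88 ± 0.45. Of 26 genes of oxidative stress and NRF2, the regulator of antioxidant genes, 21 were below 0 (median -0.24), led by HMOX1 at -1.41 ± 0.76, ABCC3 at -1.29 ± 0.65, UGDH at -1.12 ± 0.65 and TXNRD1 at -1.01 ± 0.41. In the unfolded protein response 19 of 27 genes were above 0 (median 0.16), with TRIB3 at 1.14 ± 0.71, DDIT3 at 0.96 ± 0.34 and SEL1L at 0.91 ± 0.43. ASNS, asparagine synthetase, was at 1.10 in A549, 0.80 in SAOS and 1.10 in H1299.

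In cholesterol synthesis 18 of 25 genes were above 0 (median 0.18), with HSD17B7 at 0.61 ± 0.23 and FDPS at 0.52 ± 0.21. Among AAA ATPases, the family to which ATAD2 belongs, 18 of 23 were above 0 (median 0.29), with the proteasome ATPases PSMC2 at 0.87 ± 0.23 and PSMC6 at 0.80 ± 0.15. The replication factor C subunits went apart, RFC5 to -1.12 ± 0.37 and RFC2 to 0.74 ± 0.42. Among chromatin and bromodomain proteins 23 of 32 were below 0 (median -0.10), with TRIM24 at -0.87 ± 0.36 and BRD8 at -0.65 ± 0.42.

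These 7 lists passed camera with its preset correlation, the other 6 beside the proteasome at adjusted p of 0.0042 for NRF2, 0.00914 for oxidative phosphorylation, 0.0139 for AAA ATPases, 0.0154 for cholesterol synthesis, 0.0248 for the unfolded protein response and 0.0365 for chromatin and bromodomain proteins. With an estimated correlation none of the 7 held: adjusted p = 0.753 for oxidative phosphorylation and adjusted p = 0.631 for each of the others. fry passed 0 of 27 lists in 1 direction (lowest adjusted p 0.161; 6 at an unadjusted p under 0.05) and 14 for change in either direction. The AAA ATPase list without its 6 proteasome subunits had a camera adjusted p of 0.213. Adjusted over the list alone, 7 proteasome genes passed (7 higher), 10 of oxidative phosphorylation (8 higher, 2 lower), 5 of NRF2 (5 lower), 7 of the unfolded protein response (6 higher, 1 lower), 5 AAA ATPases (4 higher, 1 lower) and 0 of cholesterol synthesis and of chromatin. Adjusted over all 14473 genes, only ASNS of these 7 lists passed, at a limma adjusted p of 0.0469.

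Cell cycle genes went in both directions. Of 35 E2F targets 21 were above 0 (median 0.14), with RRM2 at 2.06, MCM10 at 0.91 ± 0.38, CCNA2 at 0.88 ± 0.26 and E2F1 at 0.82 ± 0.42. Of 38 G2/M and mitosis genes 27 were above 0 (median 0.17), with CKS1B at 0.75 ± 0.32, while TOP2A was at -1.06 ± 0.47 and ECT2 at -0.57 ± 0.11. Of 30 MYC targets 21 were above 0 (median 0.11), with ODC1 at 2.15, LDHA at 1.36 ± 0.24 and CDK4 at 0.94 ± 0.06 and with NOLC1 at -1.03 ± 0.19. Of 20 histone genes 15 were below 0 (median -0.15); H1-2 was at -0.71 ± 0.41 and H3C1 at -0.63 ± 0.32, and the variants H2AZ1 at 0.64 ± 0.33 and H2AX at 0.62 ± 0.31. The camera adjusted p was 0.0748 for E2F targets, 0.0516 for G2/M, 0.108 for MYC targets and 0.0715 for histones. Adjusted over the list alone, 7, 0, 6 and 8 genes passed in these lists, and over all genes 1, 0, 4 and 0.

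In the apoptosis list (18 of 25 above 0, median 0.14, camera adjusted p 0.104) MCL1, an inhibitor of apoptosis, was at 1.28 ± 0.46, CYCS at 0.92 ± 0.46 and BAK1 at 0.64 ± 0.10, and these 3 passed adjusted over the list alone. Among heat shock genes (median 0.28, adjusted p 0.422) HSPA4 was at -1.22 ± 0.16 and CHORDC1 at 1.09 ± 0.46, and 3 of 19 passed adjusted over the list alone, HSPA4 also over all genes (limma adjusted p 0.0415). In the RNA interference machinery (median -0.22, adjusted p 0.104) XPO5 was at -0.54 ± 0.11 and ADAR at 0.49 ± 0.28, with 5 of 11 genes passing adjusted over the list alone. Nuclear receptor targets had a median of -0.09 (adjusted p 0.121), and CCND1 was the 1 gene that passed adjusted over the list alone and over all genes (0.0495). Interferon genes had a median of 0.02 (adjusted p 0.548), with ISG20 at 0.97 ± 0.22 and GBP1 at 0.67 ± 0.19 passing adjusted over the list alone. In the hypoxia list (median 0.04, adjusted p 0.886) PFKFB4 at 0.81 ± 0.39, ANKRD37 at 0.67 ± 0.29 and P4HA1 at 0.52 ± 0.10 passed likewise.

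In the list of matrix and epithelial-mesenchymal genes 17 of 35 were above 0 (adjusted p 0.847). COL4A1, a basement membrane collagen, was at -2.36 in A549, -3.40 in SAOS and -0.45 in H1299, the collagenase MMP1 had a mean of 1.55 ± 0.59 and CCN2 of -1.43 ± 0.98. MMP1 was among 2 genes that passed adjusted over the list alone. The median was 0.12 for p53 targets (adjusted p 0.422), 0.19 for NF-kB (0.300), 0.03 for ribosomal proteins (0.971), 0.02 for cancer-testis genes (0.730), -0.02 for lung epithelium markers (0.548), -0.07 for osteoblast markers (0.279), 0.10 for blood cell markers (0.300) and -0.01 for fibroblast and endothelial markers (0.712), and 0 genes passed adjusted over each list alone. Reference genes had a median of 0.07 (0.682), and ACTB at -0.80 ± 0.32 and TUBA1B at 0.49 ± 0.03 passed adjusted over the list alone. Mean, median and camera's direction differed in sign for cancer-testis genes (mean -0.01, median 0.02, up), matrix genes (mean 0.0061, median -0.0038, down) and ribosomal proteins (mean 0.02, median 0.03, down).

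In A549 cells the highest named transcripts were LOC151760 at 3.75, smooth muscle actin (ACTA2) at 3.03, the LIM-domain protein FHL2 at 2.98, HOXB6 at 2.91, ANTXR2 at 2.91 and SPANXB1 at 2.64. The lowest were SLC51B at -2.80, the zinc transporter SLC39A8 at -2.74, OPN3 at -2.70, STRAP at -2.69, ATOH8 at -2.67 and NEUROD1 at -2.61, whose other probe was at 0.28. LOC151760 was at 0.34 in SAOS and -0.09 in H1299, and SLC51B at -0.01 and -0.16. By the size rule 628 probes were counted in A549, 320 higher and 308 lower, against 237 of that size with opposite signs on the 2 arrays. A549 had 1 extract per condition, so there is no replicate check and no p.

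In SAOS cells the highest named transcripts were ACTG1 at 3.02 (other probe 2.46), ANTXR2 at 2.94, CTDSP2 at 2.70, LRP8 at 2.69, the translation factor subunit EIF3J at 2.55 and ATP5MJ at 2.55. For LRP8 the 2 arrays gave 4.34 and 1.05, and its other probe was at -0.01. The lowest were COL4A1 at -3.40, STRAP at -3.17, the actin-binding tropomyosin TPM1 at -2.71 (other probe -0.36), the cancer-testis gene MAGEC1 at -2.62, PAIP1 at -2.35 and SCRN1 at -2.33. COL4A1 was at -2.36 in A549 and -0.45 in H1299, and MAGEC1 at -0.27 and -0.12. The size rule counted 435 probes in SAOS, 243 higher and 192 lower, against 286 with opposite signs, again without a replicate.

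In H1299 cells the highest named transcripts were COX20 at 2.65, ATP5MJ at 2.52, the chaperone DNAJB6 at 2.26 (other probe -0.57), HOXB6 at 2.20, ODC1 at 2.14 and HYPK at 1.83. The lowest were STRAP at -2.64, CEMIP2 at -2.34, the mitochondrial pyrophosphatase PPA2 at -2.16, ID3, an inhibitor of helix-loop-helix factors, at -1.97, SLC44A1 at -1.91 (other probe 0.000146) and the ectonucleotidase NT5E at -1.86. NT5E was at 0.21 in A549 and 0.08 in SAOS. The size rule counted 419 probes in H1299, 182 higher and 237 lower, against 241 with opposite signs, and no replicate stood behind them. With a rule of 0.58 in place of 1 the counts were 2125 in A549, 1731 in SAOS and 1550 in H1299.

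Within single lines, p53 targets stood highest in A549, where 21 of 26 genes were above 0 and the median was 0.53, above all 10000 random lists (percentile 100). The p53 target GADD45A was at 2.25 in A549, TP53I3 at 1.38, CDKN1A, a cyclin-dependent kinase inhibitor, at 0.99 and TIGAR at 0.83. FDXR at 2.23, the pro-apoptotic BBC3 at 1.93 and MDM2 at 0.01 were picked out after their values were seen. The list's median was -0.04 in SAOS (percentile 26.1) and -0.10 in H1299 (percentile 3.37). The NF-kB list had a median of 0.49 in A549 (percentile 100), with the chemokine CCL20 at 2.51, PTGS2 at 1.29 and TNFAIP3 at 1.23, against 0.01 in SAOS (54.1) and -0.05 in H1299 (17.0). The single arrays of these 2 lines parted by dye. NF-kB medians were -0.45 (percentile 0.04) and -0.29 (0.78) on their Cy3 arrays and 0.11 (69.2) and 0.06 (49.4) on their Cy5 arrays. The apoptosis list had a median of 0.39 in A549 (percentile 99.98), 0.09 in SAOS (89.7) and 0.01 in H1299 (52.5). Its A549 value rested on 1 array, with medians of -0.02 (percentile 44.0) on the Cy3 array and 0.61 (99.95) on the Cy5 array. NRF2 targets had a median of -0.54 in A549 (percentile 0), with ABCC3 at -1.97, HMOX1 at -1.93 and UGDH at -1.87, against -0.02 in SAOS (32.9) and -0.10 in H1299 (3.43). On the Cy3 arrays they also lay below random lists in SAOS (-0.29, percentile 1.56) and H1299 (-0.36, 0.12). On the Cy5 arrays of SAOS (0.02, 38.1) and H1299 (-0.12, 7.17) they did not.

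E2F targets had a median of 0.18 in SAOS (percentile 99.8) and 0.30 in H1299 (99.99), and of -0.12 in A549 (2.51); of the single SAOS arrays, 1 lay within random lists (83.4). G2/M genes stood at 0.18 in SAOS (99.9), 0.25 in H1299 (100) and 0.10 in A549 (85.6), with 1 H1299 array within random lists (97.0). MYC targets had medians of 0.17, 0.16 and -0.02 in SAOS, H1299 and A549, at percentiles 99.6, 98.9 and 33.8, but both single H1299 arrays (96.9 and 91.5) and 1 SAOS array (96.4) lay within random lists. Heat shock genes had a median of 0.53 in SAOS (percentile 100; 13 of 19 above 0), 0.31 in H1299 (99.95; 12 of 19, with 4 at or below -0.58) and -0.03 in A549 (28.4; 8 of 19). HSP90AA1 was at 1.49 in H1299 and 0.43 in SAOS, and HSPE1 at 1.20 and 0.97, while HSPA4 was at -1.04 and -1.30. Cholesterol synthesis stood at 0.28 in SAOS (99.99), 0.16 in H1299 (98.5) and 0.06 in A549 (67.8), and the H1299 value rested on 1 array (medians 0.0065 and 0.44, percentiles 59.2 and 99.9), while 1 SAOS array lay within random lists (95.5). The proteasome list lay above the central 95% of random lists in each line, with medians of 0.40 in A549, 0.15 in SAOS and 0.49 in H1299, as did oxidative phosphorylation (0.35, 0.14 and 0.36) and the unfolded protein response (0.21, 0.22 and 0.14). On single arrays this did not always hold. In SAOS both arrays lay within random lists for the proteasome (94.5 and 97.49), oxidative phosphorylation (80.0 and 74.8) and the unfolded protein response (87.2 and 96.2), as did 1 array of A549 (78.4) and 1 of H1299 (92.0) for the last. Ribosomal protein genes stood at 0.06, -0.02 and 0.01.

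**Figure D2:**
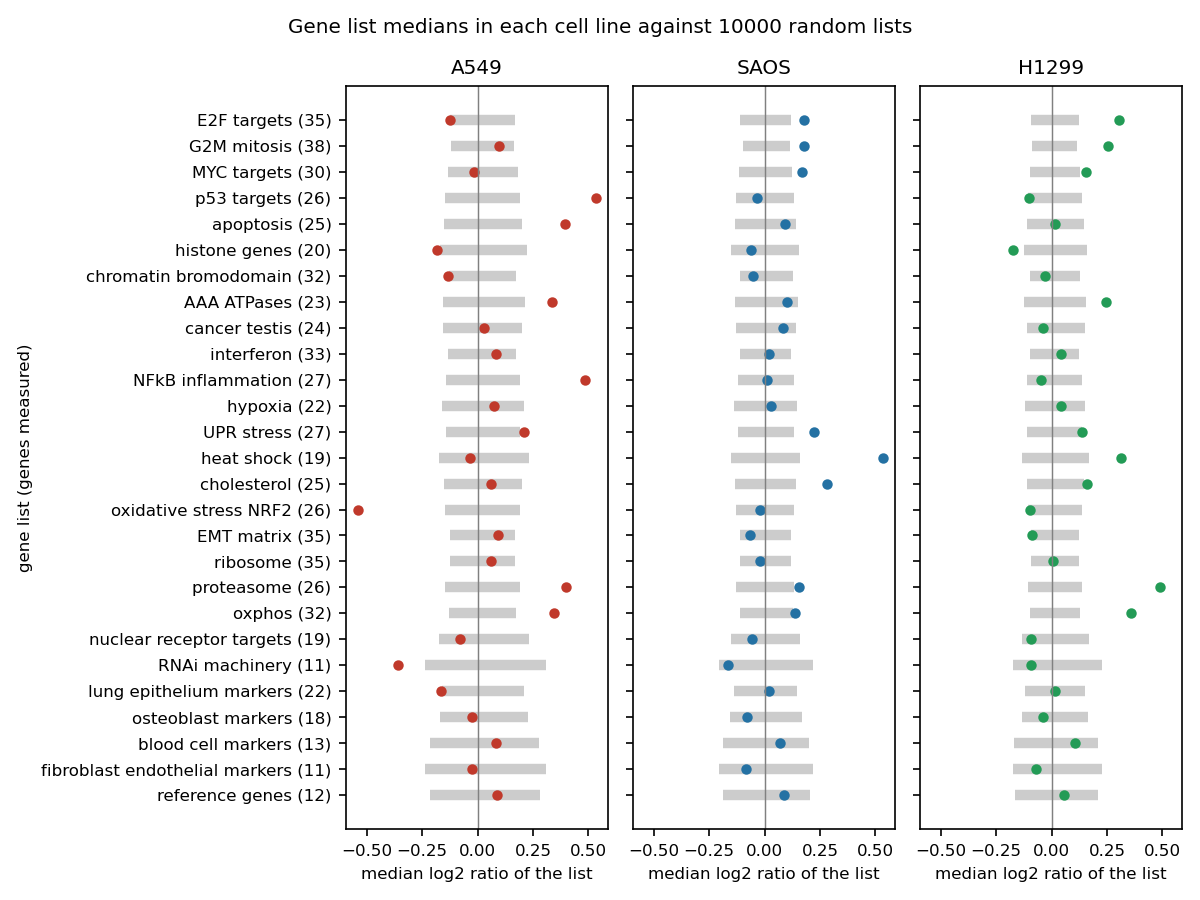
Median log2 ratio of each of the 27 gene lists (points; number of measured genes in brackets) in A549, SAOS and H1299, with grey bars for the central 95% of 10000 random lists of the same size. p53 targets lie at 0.53 in A549, -0.04 in SAOS and -0.10 in H1299.

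Of 27 lists, 12 lay outside the central 95% of random lists in A549 (7 above, 5 below), 8 in SAOS (8 above, 0 below) and 10 in H1299 (9 above, 1 below). By chance 1.35 would in each line, if the lists held unrelated genes. In some lists the genes move together, with an estimated correlation of 0.439 for oxidative phosphorylation and 0.558 for NF-kB. It was 0.413 for p53 targets, 0.396 for heat shock and 0.383 for the proteasome. For such lists 1.35 is too low, so the counts do not measure evidence. Below in A549 were, beside NRF2, lung epithelium markers (median -0.16, percentile 2.18; single arrays 2.14 and 4.31), RNA interference machinery (-0.36, 0.37; 29.5 and 5.87), histones (-0.18, 1.77; 89.3 and 2.12) and chromatin (-0.13, 2.35; 7.18 and 18.9). Histones were also the 1 list below in H1299 (-0.17, 0.51; 65.4 and 0.04). AAA ATPases lay above in A549 (0.33, 99.8; 96.9 and 98.4) and H1299 (0.25, 99.8; 99.9 and 92.1). Of these 30 results, 11 lay outside on the same side on both single arrays of the line (5 in A549, 2 in SAOS and 4 in H1299) and 6 on neither. With the second array of each line left out the counts fell from 30 lists in the 3 lines to 19. No test of the difference between lines was possible with 1 replicate each, and the A549 slides were numbered apart from those of the other lines.

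**Figure D3:**
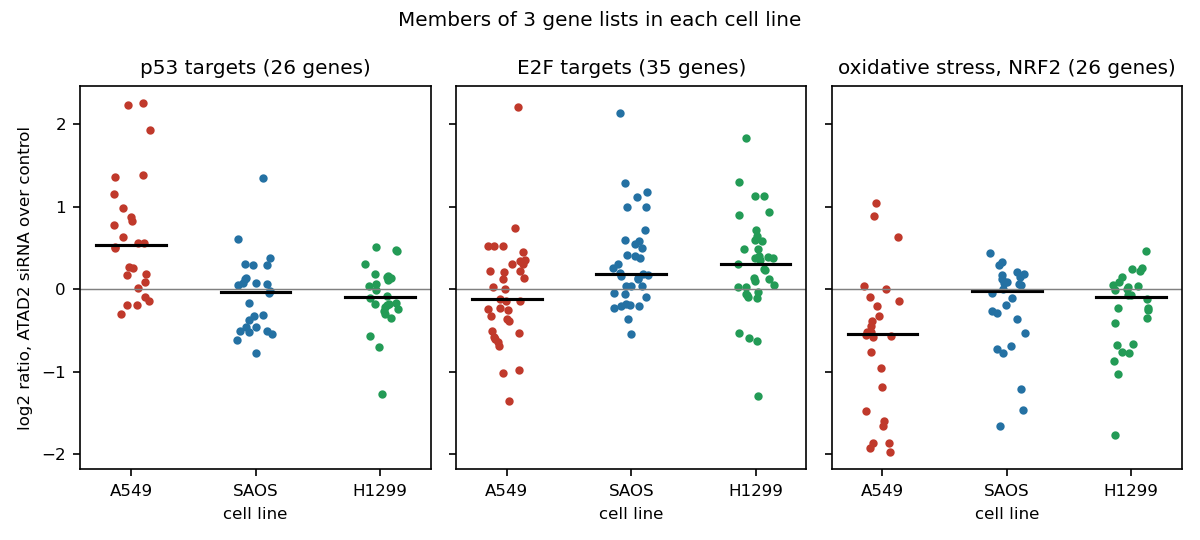
Log2 ratios of the members of 3 gene lists in each line (points, mean of 2 arrays) with the list median (black line). The medians of p53 targets are 0.53, -0.04 and -0.10 in A549, SAOS and H1299, those of E2F targets -0.12, 0.18 and 0.30, and those of oxidative stress and NRF2 genes -0.54, -0.02 and -0.10.

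The lines overlapped in the probes past the size rule. STRAP was past the size rule in each line, as one of 20 probes lower in all 3 lines; 44 probes were higher in all 3. A549 and SAOS shared 82 higher and 39 lower probes, where independent lists would share 2.87 and 2.19. A549 and H1299 shared 66 and 92 (2.15 and 2.70 for independent lists), and SAOS and H1299 68 and 37 (1.63 and 1.68). Across 27057 probes, which are not independent replicates, the line means correlated at r = 0.312 for A549 with SAOS, 0.372 for A549 with H1299 and 0.376 for SAOS with H1299 (Spearman's rho 0.268, 0.317 and 0.327). With 1 array per line and opposite dyes, the median r was -0.126.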

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

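The tests of dye effects, array spread and slide batch for p53 targets were chosen only after the result was seen, and the added list of p53 targets was chosen after the first list's result but before its own values were seen. The genes and lists here stand out because both arrays of 1 line moved one way and both arrays of another line the opposite way. None of these differences between lines was tested, since each line is 1 replicate.

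Among p53 targets, FDXR was 3.00 higher in A549 than in SAOS on the log2 scale and 2.40 higher than in H1299, and BBC3 was 2.30 and 2.64 higher. The median of the whole list was 0.57 higher in A549 than in SAOS and 0.63 higher than in H1299. A dye effect shared by the lines cancels in A549 minus the other lines. One particular to A549 would turn this difference between the 2 dye orientations. Its median was 0.52 and 0.65 in the 2 orientations, at percentile 99.99 or above among random lists in both. This argues against a dye effect equal on both arrays of a line as the whole cause. After scaling of the arrays to one spread the difference lay at percentile 100. Random lists were scaled alike, so this percentile could hardly change. It does not decide whether the spread of the A549 arrays plays a part. In an added list of 31 other p53 targets the same difference lay at percentile 99.94 (medians 0.31 in A549, 0.14 in SAOS and 0.03 in H1299), although SAOS by itself also reached percentile 98.4. p53 status may therefore account for the difference, as a hypothesis, since A549 has wild-type p53 and SAOS and H1299 lack it. However, MDM2, a classical target, was at 0.01 in A549. A549 also parted from the other lines in other first lists, at percentile 100 for NF-kB and 0 for NRF2, heat shock and E2F targets. Moreover, 0 of the slide ranges held A549 and another line, so a slide batch cannot be told apart from p53 status.

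BIK, a pro-apoptotic gene, was 2.11 higher in A549 than in H1299 and 0.84 higher in SAOS than in H1299, with its 2 A549 arrays far apart (0.21 and 3.00). CCL20 was 3.39 higher in A549 than in SAOS, and SAOS minus H1299 was -1.05. CXCL8 was 2.26 higher in A549 than in SAOS and 0.64 higher than in H1299. For the glucose transporter gene SLC2A3, A549 minus SAOS was -2.33 and A549 minus H1299 -1.47. For CA12, A549 minus H1299 was -1.54. LUM differed by 1.77 between A549 and SAOS and by -1.10 between SAOS and H1299, with 0.13 and 2.14 on the A549 arrays. LRP8 was 3.01 higher in SAOS than in H1299, where its 2 SAOS arrays were themselves far apart (4.34 and 1.05). SLC44A1 differed by -1.60 between A549 and SAOS and by 2.44 between SAOS and H1299, with -2.09 and -0.06 on the A549 arrays.

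For E2F targets the list median of A549 minus SAOS was -0.30 and of A549 minus H1299 -0.43. For heat shock genes the corresponding differences were -0.57 and -0.35, and for matrix and epithelial-mesenchymal genes 0.16 and 0.18. Smaller ones came from list medians near 0, whose signs on single arrays differed although the line medians lay close together. These were interferon genes (A549 minus H1299 0.0397, SAOS minus H1299 -0.0244), hypoxia (A549 minus SAOS 0.0480) and fibroblast and endothelial markers (A549 minus SAOS 0.0567, A549 minus H1299 0.0447). Such differences of medians do not settle whether the lines differ. Taken gene by gene, A549 minus the other lines had a median of 0.04 for hypoxia (percentile 62.8 among random lists). It was 0.16 for interferon genes (97.6, by dye 99.7 and 79.6). For fibroblast and endothelial markers it was 0.27 (97.55, by dye 94.9 and 92.2). The SAOS minus H1299 difference of interferon genes and that of hypoxia run against the single arrays. Interferon medians were 0.06 and 0.14 on the SAOS arrays and -0.04 and -0.03 on the H1299 arrays, and hypoxia medians -0.13 and -0.01 on the A549 arrays and 0.05 and 0.11 on the SAOS arrays.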

How the results depend on the processing

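Named probes alone, turned signs, the adjusted threshold of 0.10 and the shortened AAA ATPase list were chosen only after the result was seen. The common response stayed at 0 probes with no centring, scaling, quantile normalisation, a robust prior and without each line or array (limma; 4292 at an unadjusted p under 0.05). It was 2044 with 6 arrays and the line as block, 1561 with a dye coefficient and 752 without the 25% of probes with the largest dye-swap difference. Named probes alone gave 98, and averaging the named probes of a gene gave 133 genes. At a limma adjusted p under 0.10 the count was 999. The 6-array fits take technical arrays as separate values; the cause of the other changes was not tested. With the sign of the 3 Cy5 arrays turned, 5062 probes passed; dye effects would add up there if the deposited values run the same way on all arrays, and the response would if they do not.

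Counts by the size rule kept within 1.5 times under no centring, scaling and quantile normalisation. Both arrays at 0.58 gave 2125, 1731 and 1550 probes in A549, SAOS and H1299, and the mean rule 1523, 971 and 1016. Gene means, which also leave out unnamed probes, gave 346, 260 and 176. Of the probes past the main rule, 419, 318 and 223 were named, so part of that fall comes from leaving out unnamed probes. The cause of the rest was not tested. Single arrays gave 2741 to 3856 in A549, 2342 to 2582 in SAOS and 2300 to 2372 in H1299.

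Of 27 lists, 7 passed camera, 0 with an estimated correlation, 0 with fry, and 3 to 8 without 1 line (3 without H1299, 6 without SAOS, 8 without A549). Without A549, the E2F, G2/M, MYC and heat shock lists passed, at adjusted p of 0.000968, 0.0136, 0.0237 and 0.0237, while oxidative phosphorylation (0.0757), the unfolded protein response (0.0544) and chromatin (0.213) did not. The proteasome and NRF2 lists passed without each line in turn. The sign of a list mean turned in 8 cases, 6 of them without A549: p53 (0.16 to -0.08), NF-kB (0.12 to -0.13), matrix (0.0061 to -0.11), ribosomal (0.02 to -0.02), cancer-testis (-0.01 to 0.03) and lung markers (-0.04 to 0.03). The others were matrix under scaling (-0.0045) and fibroblast and endothelial markers without SAOS (-0.04 to 0.03). Lists outside random lists numbered 30 in the 3 lines, and 19 to 25 with 1 array per line. The median correlation between lines was 0.372, was 0.417 and 0.461 with 1 array per line of the same dye, and turned to -0.126 with opposite dyes. The named genes were chosen for 1 direction on all arrays, so their direction under these alternatives shows nothing of stability; 96 of their values passed the threshold.

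Missing values were not varied, since none were missing, and turning the sign of all arrays only mirrors the values. Signal over background was not at hand, so dim probes stayed in. No paired analysis was possible because each array already compares both conditions.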

Other observations

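The tests of the proteasome and oxidative phosphorylation pattern and of transcripts lower than ATAD2 were chosen only after the result was seen; the NF-kB and NRF2 lists were added after the first lists' results but before their own values were seen.

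Actin genes went apart. The ACTB spots, 321 on each array, had means from -1.20 to -0.41, below 0 on all 6 arrays, with an SD between spots of 0.31 to 0.47. GAPDH, on 272 spots, had means from -0.06 to 0.41. In contrast ACTG1, the other cytoplasmic actin, was at 1.85 in A549, 3.02 in SAOS and 1.44 in H1299, and the smooth muscle actin ACTA2 at 3.03, 0.85 and 0.40. Tropomyosin TPM1 was at -2.10, -2.71 and -1.68, with its other probe at -0.36 in SAOS. COX20 and ATP5MJ, both mitochondrial, were higher in every line, at 2.15, 1.06 and 2.65 and at 1.75, 2.55 and 2.52. NEUROD1 was at -2.61 in A549, -0.04 in SAOS and -2.21 in H1299, and ID3 at -0.01, -1.42 and -1.97.

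Proteasome and oxidative phosphorylation genes were higher together in A549 and H1299, with medians over both lines of 0.43 (95% bootstrap interval 0.23 to 0.62) and 0.38 (0.18 to 0.51). The bootstrap intervals here resample the genes of a list, which are not independent replicates. They hold no spread between treatments or lines, and the lists and lines were picked for being high. A ratio bias that depends on spot intensity may be part of the higher values. Ribosomal protein genes stayed near 0 (upper bound of their median 0.0772), but this decides nothing, since no intensities were at hand and saturated spots would be compressed toward 0. A dye effect equal on both arrays of a line would turn a list's median on 1 of them and cancel in their mean. The medians of both lists were above 0 on the 4 arrays (0.20 to 0.57). The lowest lower bound over the dye-balanced line means was 0.14. The lists and lines were picked by these means and an equal dye effect cancels in them, so this bound decides nothing. Only the shared sign on the 4 arrays argues against an equal dye effect as the whole cause. An unequal dye effect is left open by this. On the A549 Cy3 array the proteasome interval included 0 (-0.01 to 0.40), while the other single-array intervals did not. No biological explanation was tested.

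In every line 23 probes, 16 of them named, were lower than ATAD2, the gene the siRNA targets, and 99 had a lower mean. Off-target action of an siRNA may be part of this, and so may a compressed ratio of the single ATAD2 probe. The 23 probes decide neither, because no other siRNA against ATAD2 was analysed here. They cannot be told apart from transcripts that depend on ATAD2.

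A wider shift of NF-kB targets in A549 was a hypothesis from the first list (median 0.49). In an added list of 27 other targets the A549 median was 0.14, at percentile 91.8, which lies within random lists, although its difference from the other lines lay at percentile 98.5. For NRF2 the first list stood at -0.54 in A549, but an added list of 19 other targets stood at -0.07, at percentile 18.4. By the A549 median, the measure set beforehand for these 2 lists, neither hypothesis was borne out by its added list. By A549 minus the other lines, the measure printed for the added p53 list, NF-kB lay outside random lists and NRF2 (percentile 21.2) did not. The added p53 list lay outside by both measures, with its A549 median at percentile 99.96. BCL2A1 (2.29) and GPX2 (-2.14), picked after their values were seen, moved in A549 with the first lists.

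Turning the signs of the lines gives 4 splits of the 3 lines, too few for a share under 0.05. At an adjusted p under 0.05, limma gave 0 probes in the real arrangement and at most 0 in the others, so all 4 gave as many. At an unadjusted p under 0.05 the real arrangement gave 4292 and the highest other 694, so 1 of 4 gave as many.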
